A study of Mus musculus with 4 samples.

How the data were processed

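Messenger RNA was sequenced from bulk hepatocellular carcinoma tissue of 4 mice that carried an albumin-driven Cre and a Myc transgene at the H11 locus, which gives spontaneous c-Myc-driven liver tumours. Per the labels, 2 mice had Tfrc deleted in the liver and 2 were wild type, so replicates are separate animals. RNA was isolated with a column kit and libraries were made with a poly(A) mRNA kit, per the labels' protocols. The strandedness of the library and of the counting is not given in the sources used here, so reads of a gene and its antisense partner are treated as inseparable.

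The authors deposited 1 table of 55487 genes with Ensembl identifiers, gene spans, raw counts and FPKM for all 4 libraries. HISAT2, SAMtools 1.3.1, StringTie and edgeR are named with the mm10 build, per the submitters' processing notes, without the role of each. The deposited counts were whole numbers. The deposited FPKM equalled the count scaled by a fixed gene length and the column total for 100% of the genes with at least 10 counts, within 1%, so FPKM held no information beyond the counts and was not tested. Of the identifiers, 55141 matched a gene symbol and 346 did not. The deposited spans equalled those of GENCODE M21 for 99.4% of the matched genes. Where several identifiers shared a symbol (213 identifiers), the one with the highest total kept the plain symbol.

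Total counts were 16414883 and 17052943 in wild type replicates 1 and 2, and 15918349 and 16421439 in knockout replicates 1 and 2. A floor of 3 counts in a library corresponds to 0.176 to 0.188 CPM. Such floors and the Wilson intervals of count shares cover counting error only, because the reads carry no molecular identifiers.

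Genes with low counts were removed with edgeR's filterByExpr by group, which left 16310 genes. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Means and SDs are of TMM-scaled CPM. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so single values were tested only in the model fitted across genes. With 2 libraries in a group, the spread comes largely from pooling over genes.

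Before the data were examined, 47 gene lists of pathways, cell types and tissue quality were written, with 1084 symbols of which 1072 were found in the table. The 46 lists with at least 5 tested members entered limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided and adjusted over the lists. Members were also adjusted over the list alone. The rule for named genes was fixed at the same time. It took Tfrc, Myc and Alb, then up to 12 genes per direction among those past the threshold whose libraries separated the groups, with a mean of at least 5 CPM and no predicted or clone name. If fewer than 12 passed, all were taken and the set was filled to 5 per direction by the smallest unadjusted p under the same rules for level and name. For each list described, up to 4 tested members with the smallest p were named, or for a cell type or quality list without a change the 2 members with the highest level. Gm43305, Gm20716, Sult2a1, Cyp2b9, Reg3g, Cela1, the nuclear copies of mitochondrial genes and a platelet list were chosen after values were seen. Of the genes this rule takes, 2 are not reported here.

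The alternatives were DESeq2's size factors or library totals in place of TMM, no filter or a filter at a mean of 5 CPM, DESeq2 (1.42.0), limma-voom, a replicate block, an added limit on fold change, camera with an estimated correlation, fry, and leaving out each library in turn. Leaving out the mitochondrial genes with 10 similar nuclear genes was added after seeing the data. In each fit without a library, the lone sample of its group was assumed to vary like the other group.

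The gene test was tested on simulated data for the knockout against wild type comparison, drawn for 16310 genes with the real means, dispersions and library sizes and 200 changed genes. It recovered 0 of 50 genes changed 2-fold, 21 of 50 changed 4-fold, 40 of 50 changed 8-fold and 44 of 50 changed 16-fold, with 13 false calls. Those false calls were a larger share of all calls than the threshold of 0.05. The recovered shares do not give the sensitivity in the real data. There 19 genes differed at least 8-fold between every library of the labelled groups, and 0 genes passed. In the same simulation 4 of 200 unshifted random lists had an unadjusted camera p under 0.05. The simulated genes were independent of each other, so this count does not cover correlated lists.

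Transcripts of mitochondrial genes were aligned to those of similar genes in an insertion on chromosome 1 with GENCODE M21 to pair each gene with its copy. How the authors' counting treated reads that map to both is not given in the sources used here, so these counts are uncertain. Reads were not used here.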

Results

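Bulk tumour RNA was measured in 4 mice with c-Myc-driven liver cancer, of which the labels give 2 as wild type and 2 as having Tfrc deleted in the liver by an albumin-driven Cre recombinase. The series asked how Tfrc shapes the tumour and its microenvironment. Total counts were 16414883 and 17052943 in wild type replicates 1 and 2, and 15918349 and 16421439 in knockout replicates 1 and 2. Values below are CPM, counts scaled to library size with TMM factors. Mitochondrial genes took 8.69% and 4.13% of the counts in wild type replicates 1 and 2, and 9.8% and 16.63% in knockout replicates 1 and 2. Alb, the main secreted hepatocyte protein, took 0.6% and 2.66% of counts in the wild type and 2.23% and 1.62% in the libraries labelled knockout. On the first principal component, with 48.2% of the variance, wild type replicate 2 stood apart at 86.6, against -11.2 for wild type replicate 1 and -37 and -38.5 for the libraries labelled knockout.

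Tfrc, the receptor that imports transferrin-bound iron, was not detectably lower in the libraries labelled knockout. The gene (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794, mm10) had 347 ± 160 CPM in wild type and 269 ± 91.2 CPM in knockout (SD, n = 2 each). Counts were 8441 and 3603 in wild type replicates 1 and 2, and 5407 and 3244 in knockout replicates 1 and 2, so knockout replicate 1 lay above wild type replicate 2. The log2 fold change was -0.37 (SE 0.45, 95% interval -1.44 to 0.71, edgeR quasi-likelihood adjusted p = 0.833). Without wild type replicate 1 it was 0.17. The labels name no deleted exons, and a count over the whole gene in bulk tissue includes cells that keep the gene and exons outside the deleted part. Tfrc therefore did not check the labels, and each direction below is that of the libraries labelled knockout.

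No single gene passed the threshold between the libraries labelled knockout and wild type. The clearest separations were a much lower level of villin and globin transcripts and a higher level of a few transcripts of mixed function. Of 16310 tested genes, 0 were higher and 0 lower by edgeR's quasi-likelihood test, with a smallest adjusted p of 0.0595. At an unadjusted p under 0.05 there were 1354 genes, 645 higher and 709 lower, or 8.3% of those tested. DESeq2 called 65 higher and 85 lower, and limma-voom called 0 higher and 1 lower. The count also moved with single libraries: 209 higher and 200 lower without wild type replicate 1, 29 and 39 without wild type replicate 2, and 2 and 1 without knockout replicate 2. In 42% of the tested genes the groups did not overlap, against 33.3% expected by chance for 2 against 2.

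The genes named by rank did not pass edgeR's adjusted threshold, though DESeq2 called each of those given here. Vil1, which encodes the microvillus protein villin (ENSMUSG00000026175, chromosome 1, 74409376 to 74435559), had 163 ± 43.8 CPM in wild type and 7.57 ± 3.12 CPM in knockout, a log2 fold change of -4.42 (SE 0.45, adjusted p = 0.118). The sialyltransferase gene St6galnac2 had 73 ± 6.08 against 15.6 ± 2.19 CPM, and Lmo2, a transcription cofactor of blood and endothelial cells, had 50.4 ± 7.24 against 10 ± 1.03 CPM. The adult beta-globin gene Hbb-bt had 434 ± 202 against 37.5 ± 16.2 CPM, a log2 fold change of -3.53. On the higher side, Exosc6, a subunit of the RNA exosome, had 3.17 ± 0.904 CPM in wild type and 43.2 ± 0.989 CPM in knockout (log2 fold change 3.76, SE 0.39, adjusted p = 0.118). The Polycomb-group gene Sfmbt2 had 1.89 ± 1.02 against 20.1 ± 9.03 CPM, and the cAMP phosphodiesterase gene Pde4c had 8.71 ± 2.3 against 37.9 ± 5.93 CPM. Zfp970 had 6.39 ± 0.88 against 26.2 ± 1.07 CPM, and the pseudogene Serpina4-ps1 had 8.48 ± 0.411 against 33.6 ± 4.14 CPM, each with an adjusted p of 0.386. Counts of Exosc6 are uncertain because it overlaps Aars on the same strand, and those of St6galnac2 because a second identifier and an antisense gene share its span. Genes on the opposite strand also overlap Vil1 (Usp37), Lmo2 (4931422A03Rik) and Sfmbt2 (Gm13261), so their counts may be mixed too. In knockout replicates 1 and 2, Usp37 had 219 and 251 counts, against 87 and 155 for Vil1. Serpina4-ps1 and Zfp970 belong to multigene families and may share reads with their relatives.

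**Figure D1:**
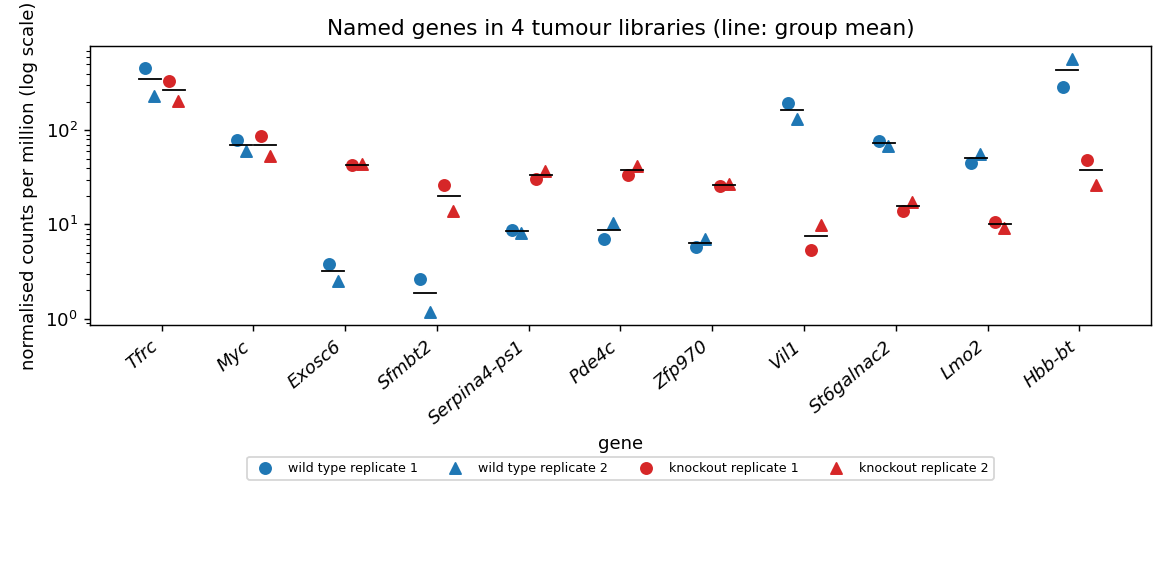
Normalised CPM on a log axis for 11 named genes, with circles for replicate 1, triangles for replicate 2, blue for wild type, red for the libraries labelled knockout and lines for group means. Tfrc and Myc overlapped between the groups, while Vil1 lay at 163 CPM on average in wild type and 7.57 CPM in knockout.

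The smallest adjusted p, 0.0595, belonged to 2 genes chosen after their values were seen. Gm43305, a non-coding transcript (chromosome 14, 54292443 to 54297456), had 1274 ± 317 CPM in wild type and 6.01 ± 2.3 CPM in knockout, a 212-fold lower level. Gm20716 (chromosome 2, 168180986 to 168230364) had 0 counts in both wild type libraries and 543 and 383 in knockout, at least 161-fold higher against a floor of 3 counts per library. Gm20716 overlaps Adnp and Dpm1 on the same strand, so its counts are uncertain.

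A Myc transgene drives these tumours. Whether its reads were counted for the Myc gene on chromosome 15 is not given in the sources used here. Myc as counted did not differ detectably between the groups, with 69.7 ± 13.8 CPM in wild type and 70 ± 23.1 CPM in knockout. Its log2 fold change was 0.01 (95% interval -0.82 to 0.83), with a sign that turned to between -0.03 and -0.01 under DESeq2's size factors, library totals, no filter, DESeq2, limma-voom and the model with replicate number. Alb had 17420 ± 17030 against 19340 ± 3578 CPM, so the wild type mice differed more from each other than the groups did. The list of 31 MYC targets of ribosome biogenesis had 14 members with a positive and 17 with a negative log2 fold change (camera adjusted p = 0.635). Ddx18, a nucleolar helicase gene, had 68 ± 8.04 against 33.5 ± 0.973 CPM and the ribosome assembly gene Bop1 122 ± 41 against 71.3 ± 14.9 CPM. Gnl3, which encodes nucleostemin, had 84.6 ± 22.1 against 132 ± 9.89 CPM, and none of these 3 passed. Bop1 moved from -0.77 to -0.38 without wild type replicate 2 and Gnl3 from 0.64 to 0.36 without wild type replicate 1. Among 35 cell cycle genes, 24 had a negative log2 fold change (median -0.14, camera adjusted p = 0.135). The list passed without wild type replicate 2 (median -0.32, adjusted p = 5.68e-03) and with no filter (adjusted p = 0.0266). The replication helicase genes Mcm6, Mcm3 and Mcm2 had log2 fold changes of -1.26, -1.04 (-0.68 without knockout replicate 2) and -0.84, and 0 members passed when adjusted over the list alone.

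Iron-handling genes showed no shared direction. Their list joins genes of uptake, storage, export and sensing, and camera tests for a shift in 1 direction. Opposite moves within the list would therefore go unseen. Of 34 tested genes for iron uptake, storage, export and sensing, 16 had a positive and 18 a negative log2 fold change (median -0.12, camera adjusted p = 0.34), and 0 passed when adjusted over the list alone or over all genes. The endosomal ferrireductase gene Steap3 had 92.2 ± 45.2 CPM in wild type and 33.7 ± 4.15 CPM in knockout (log2 fold change -1.45, SE 0.41; -0.84 without wild type replicate 2). Slc40a1, the iron exporter ferroportin, had 118 ± 10.9 against 60.7 ± 5.61 CPM (log2 fold change -0.96, SE 0.29). The ferrireductase gene Cybrd1, with only 24 and 25 counts in wild type and 6 and 3 in knockout, had a log2 fold change of -2.35 (SE 0.74). Slc25a37, the mitochondrial iron importer mitoferrin 1, had one of 0.96 (SE 0.34, and 0.63 without knockout replicate 2). Without wild type replicate 2 the median of the iron list was 0.11. In the ferroptosis list, 17 of 23 members had a negative log2 fold change (median -0.13, camera adjusted p = 0.316). Gpx4, the lipid peroxide reductase that guards against ferroptosis, had 143 ± 38.7 against 74.9 ± 28.9 CPM, and the oxidoreductase gene Por had a log2 fold change of -0.81. Hspb1 and Cbs had log2 fold changes of -1.58 and -0.49. Without wild type replicate 2, Hspb1 was at 0.66, Por at -0.49 and Cbs at -0.27, and Gpx4 moved from -0.94 to -1.43 without knockout replicate 1 and -0.59 without knockout replicate 2. Without knockout replicate 1 the ferroptosis list passed, with a median of -0.33.

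Of the 46 gene lists tested, 16 passed camera's threshold, 3 higher and 13 lower in the libraries labelled knockout. With an estimated correlation 0 lists passed (smallest adjusted p = 0.82), and by fry 0 passed (smallest adjusted p = 0.812). Other splits of the same 4 libraries gave as many calls, 22 lists for replicates 1 against 2 and 21 for the crossed split, so a call at the preset correlation is not specific to the labelled groups. By replicate number, MHC class II had a smaller camera adjusted p (2.72e-04) than by the labels (0.0123). The crossed split set wild type 1 and knockout 2 against wild type 2 and knockout 1. There ribosomal proteins (7.09e-05), NRF2 targets (1.73e-03), T cells (4.02e-03) and nuclear oxidative phosphorylation (2.92e-03) had smaller values than by the labels. The other lists of the 16 had their smallest by the labels. No list member passed over all genes with edgeR, while DESeq2 called 27, of which 11 were higher and 16 lower.

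Interferon-stimulated genes stood higher in the libraries labelled knockout. Of 33 tested members, 29 had a positive log2 fold change, 25 had both knockout libraries above both wild type libraries, and 14 passed upward when adjusted over the list alone. The list median was 1.22 on the log2 scale, or 2.32-fold (camera adjusted p = 2.76e-11; adjusted p = 0.82 with an estimated correlation). Isg15, a ubiquitin-like modifier, rose within the list from 10.7 ± 2.82 to 31.6 ± 2.02 CPM, and Rsad2, the antiviral enzyme viperin, from 5.57 ± 1.9 to 26.8 ± 15.5 CPM. The guanylate-binding protein gene Gbp6 and the antiviral GTPase gene Mx2 had log2 fold changes of 1.69 (SE 0.32) and 1.88 (SE 0.42), and edgeR adjusted p values over all genes of 0.424 and 0.545. Gbp6 belongs to a gene family whose members may share reads. Without knockout replicate 1 the median was 0.81 and Rsad2 moved from 2.26 to 1.48. By replicate number, only 3 of the 33 members were higher in replicates 2 (median -0.5, camera adjusted p = 3.06e-04 at the preset correlation). A shared sign in this list is therefore not specific to the labelled groups, though the median shift was larger by the labels.

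The T cell list also shifted up (18 of 22 members positive, median 0.54, camera adjusted p = 8.75e-03; adjusted p = 0.82 with an estimated correlation). Il7r, the receptor for interleukin 7, had a log2 fold change of 1.06, and the T cell genes Bcl11b, Cd6 and Cd5 had 1.27, 0.91 and 0.91. No member passed when adjusted over the list alone. Bcl11b was at 2.52 without wild type replicate 1, Bcl11b and Il7r were at 0.63 and 0.68 without wild type replicate 2, and Cd6 was at 0.57 without knockout replicate 1. The median was 1.01 without wild type replicate 1 and 0.06, no longer past the threshold, without wild type replicate 2. The call was also lost under DESeq2 (adjusted p = 0.11). At a filter of 5 CPM the genes named here were removed and the list was not tested.

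Markers of macrophages and neutrophils stood lower, as did a list of genes shared by leukocytes. In the macrophage and monocyte list, 25 of 30 members had a negative log2 fold change (median -0.69, camera adjusted p = 5.68e-05; adjusted p = 0.82 with an estimated correlation). Csf1r, the receptor for colony-stimulating factor 1, had 97.9 ± 7.55 CPM in wild type and 36.9 ± 9.56 CPM in knockout. The complement genes C1qb and C1qc and the mannose receptor gene Mrc1 had log2 fold changes of -1.51, -1.26 and -1.43, and 0 members passed when adjusted over the list alone. In the pan-leukocyte list 13 of 15 members were negative (median -0.73, camera adjusted p = 1.35e-04; adjusted p = 0.82 with an estimated correlation), and Lcp1, Laptm5 and Arhgdib fell when adjusted over the list alone. Rac2 had a log2 fold change of -0.86. Lcp1, which encodes the actin-bundling protein L-plastin, fell from 139 ± 5.72 to 35.6 ± 24.8 CPM (log2 fold change -1.97; -2.97 without knockout replicate 1). Without wild type replicate 1 the pan-leukocyte median was -0.47 and the call was lost. In the neutrophil list 12 of 14 members were negative (median -1.02, camera adjusted p = 2.29e-04; adjusted p = 0.82 with an estimated correlation). S100a8 and S100a9, the subunits of calprotectin, fell when adjusted over the list alone, S100a8 from 12.3 ± 9.99 to 1.28 ± 0.289 CPM. The granule genes Retnlg and Mmp8, each below a mean of 5 CPM, had log2 fold changes of -3.93 and -2.7. S100a8 moved from -3.26 to -2.03, S100a9 from -2.86 to -1.41 and Mmp8 to -1.38 without wild type replicate 2, and without knockout replicate 1 Retnlg was at -8.07. The neutrophil median was -1.65 without wild type replicate 1, -0.57 without wild type replicate 2 and -2.05 without knockout replicate 1, and the call was lost at a filter of 5 CPM.

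Kupffer cell markers, which label the resident macrophages of the liver, were lower for 16 of 17 members (median -1.29, camera adjusted p = 1.35e-04; adjusted p = 0.82 with an estimated correlation). C6, Spic, Slc40a1 and Hmox1 had log2 fold changes of -1.29, -1.54, -0.96 and -1.08, of which C6 is also a hepatocyte product. Without wild type replicate 2 the Kupffer median was -0.21 and the call was lost. The MHC class II list was negative in 12 of 12 members (median -0.56, camera adjusted p = 0.0123; adjusted p = 0.82 with an estimated correlation). Cd74, the invariant chain, and the class II chain genes H2-Aa and H2-Eb1 had log2 fold changes of -1.15, -0.79 and -0.58, and Ifi30 one of -0.87. These 4 were at -0.45, -0.38, -0.27 and -0.48 without wild type replicate 1, and Ifi30 was at -1.77 without knockout replicate 1. That call was lost without wild type replicate 1 (median -0.25) and without knockout replicate 2 (-0.32), and the median was -1.01 without knockout replicate 1. No member of either list passed when adjusted over the list alone.

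Stromal genes stood lower. Of 32 genes of fibroblasts, stellate cells and extracellular matrix, 26 had a negative log2 fold change, and 19 had both knockout libraries below both wild type libraries (median -0.72, camera adjusted p = 5.2e-07; adjusted p = 0.82 with an estimated correlation). Acta2, the smooth muscle actin of activated stellate cells, had 84.2 ± 7.92 CPM in wild type and 31.8 ± 6.32 CPM in knockout. The matrix protein gene Postn had 40.9 ± 10.1 against 16.3 ± 2.81 CPM, the basement membrane collagen gene Col4a2 had 258 ± 19.9 against 117 ± 3.05 CPM, and Des had a log2 fold change of -1.39. When adjusted over the list alone 0 members passed. Of 23 endothelial genes 19 were negative (median -0.51, camera adjusted p = 3.56e-03; adjusted p = 0.82 with an estimated correlation). Stab2, Vwf, Esam and Flt1 had log2 fold changes of -1.18, -1.54, -1.1 and -0.94, with Vwf at -0.78 and Esam at -0.67 without wild type replicate 2. The endothelial median was -0.87 without wild type replicate 1 and -0.2, with the call lost, without wild type replicate 2.

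Globin transcripts were lower by several-fold. In the erythroid list of 11 tested genes, 5 fell and 1 rose when adjusted over the list alone (median -1.17, camera adjusted p = 1.35e-04; adjusted p = 0.82 with an estimated correlation). The globin genes Hbb-bt, Hba-a2, Hba-a1 and Hbb-bs fell, with log2 fold changes of -3.53, -2.81, -3.1 and -3.31. Hba-a1 fell from 637 ± 356 to 74.5 ± 14.3 CPM. Hba-a1 and Hba-a2, and likewise Hbb-bs and Hbb-bt, are near-identical paralogs, so the split of counts within each pair is uncertain. The member that rose was Slc25a37. The list median was -1.76 without wild type replicate 1, -0.52 without wild type replicate 2 and -2.79 at a filter of 5 CPM, and the call held in each.

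Targets of hypoxia-inducible factor and glycolytic genes stood lower together. Of 25 HIF targets 22 were negative (median -0.75, camera adjusted p = 5.68e-05; adjusted p = 0.82 with an estimated correlation), with 0 passing when adjusted over the list alone. The glucose transporter gene Slc2a1 had 55.7 ± 13.5 CPM in wild type and 23.1 ± 5.06 CPM in knockout, and the hexokinase gene Hk2 had 39.1 ± 6.83 against 19.3 ± 2.42 CPM. Egln3, a prolyl hydroxylase that marks HIF for degradation, had a log2 fold change of -1.74 (-2.67 without knockout replicate 1). Epo, which encodes erythropoietin, had 62 and 41 counts in wild type against 8 and 0 in knockout. The glycolysis list shares Slc2a1, Hk2, Ldha and Pgk1, all negative, with the HIF list. In it 16 of 22 members were negative (median -0.77, camera adjusted p = 1.43e-03, and adjusted p = 0.82 with an estimated correlation). Pkm and Hk1 had log2 fold changes of -1.52 and -0.98, with Pkm at -2.6 without knockout replicate 1 and -0.91 without knockout replicate 2. The glycolysis median was -0.47 without wild type replicate 2 and -0.52, with the call lost, without knockout replicate 2.

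**Figure D2:**
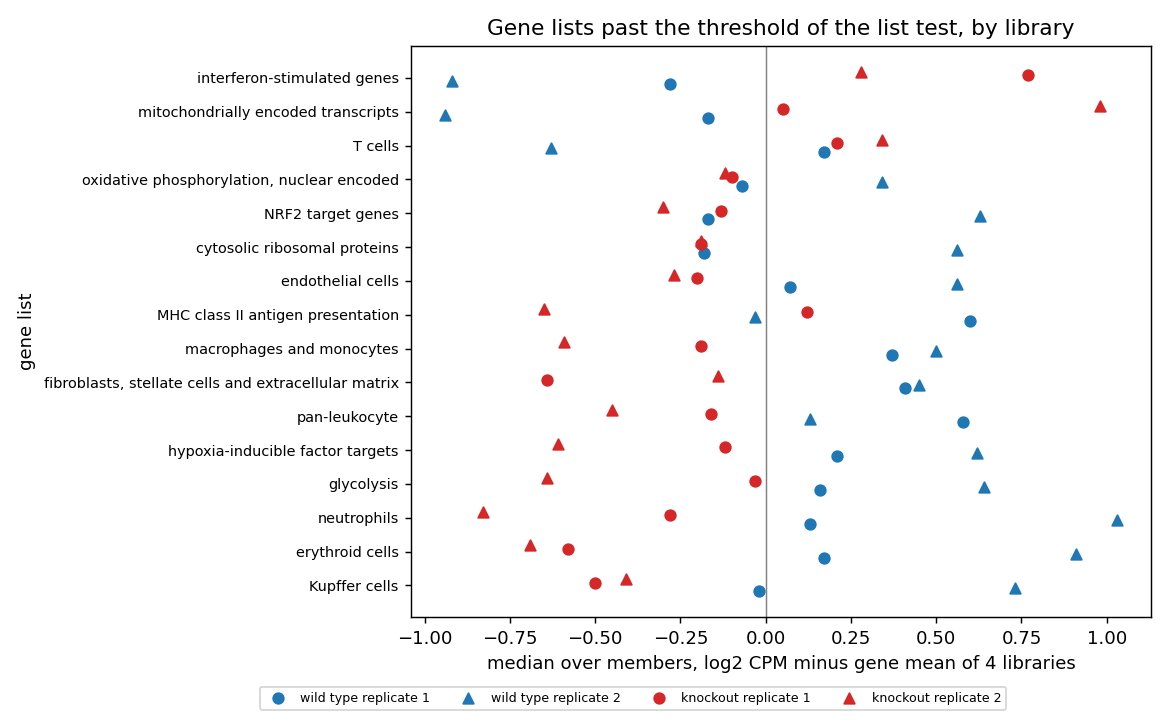
Median over the members of each of the 16 gene lists past camera's threshold of log2 CPM minus the gene's mean over 4 libraries, with 1 point per library, circles for replicate 1 and triangles for replicate 2, blue for wild type and red for the libraries labelled knockout. Interferon-stimulated genes were at 0.77 and 0.28 in knockout and at -0.28 and -0.92 in wild type, while for ribosomal proteins wild type replicate 2 stood alone at 0.56.

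Nuclear and mitochondrial genes of respiration stood on opposite sides. All 15 mitochondrially encoded transcripts had a positive log2 fold change (median 1.01, camera adjusted p = 1.97e-05; adjusted p = 0.82 with an estimated correlation). mt-Atp6, a subunit of ATP synthase, rose when adjusted over the list alone, from 844 ± 69.5 to 9245 ± 3567 CPM, and mt-Atp8, mt-Rnr1 and mt-Nd4l had log2 fold changes of 1.77, 1.01 and 1.88. The list median was 0.39 and mt-Rnr1 0.33 without knockout replicate 2, and mt-Nd4l was at 4.465 without wild type replicate 1 and 1.01 without wild type replicate 2. Counts of mt-Atp6 are uncertain, since its nuclear copy Gm10925 (chromosome 1, 24613974 to 24614651) is identical to it over 678 bases. Of the counts given to this pair, mt-Atp6 held 16.5% (95% Wilson interval 16.3 to 16.7) and 17.3% (17 to 17.6) in wild type replicates 1 and 2, and 48.8% (48.6 to 49) and 48.8% (48.7 to 49) in knockout replicates 1 and 2. Of 38 nuclear genes of oxidative phosphorylation, 34 were negative (median -0.32, camera adjusted p = 8.32e-03; adjusted p = 0.82 with an estimated correlation). Ndufb5 and Ndufa2 of complex I had log2 fold changes of -0.63 and -0.8 (-0.39 for Ndufa2 without wild type replicate 2), and Cox7c of complex IV one of 0.72. The median was -0.56 without wild type replicate 1, and the call was lost without wild type replicate 2 (-0.02) and without knockout replicate 2 (-0.26). The same opposition appeared in the crossed split. There 0 of 15 mitochondrial transcripts (camera adjusted p = 2.24e-05) and 30 of 38 nuclear genes (adjusted p = 2.92e-03) were positive. By replicate number 15 of 15 mitochondrial transcripts and 32 of 38 nuclear genes were higher in replicates 2. A shared sign and opposite sides are therefore not specific to the labelled groups.

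**Figure D3:**
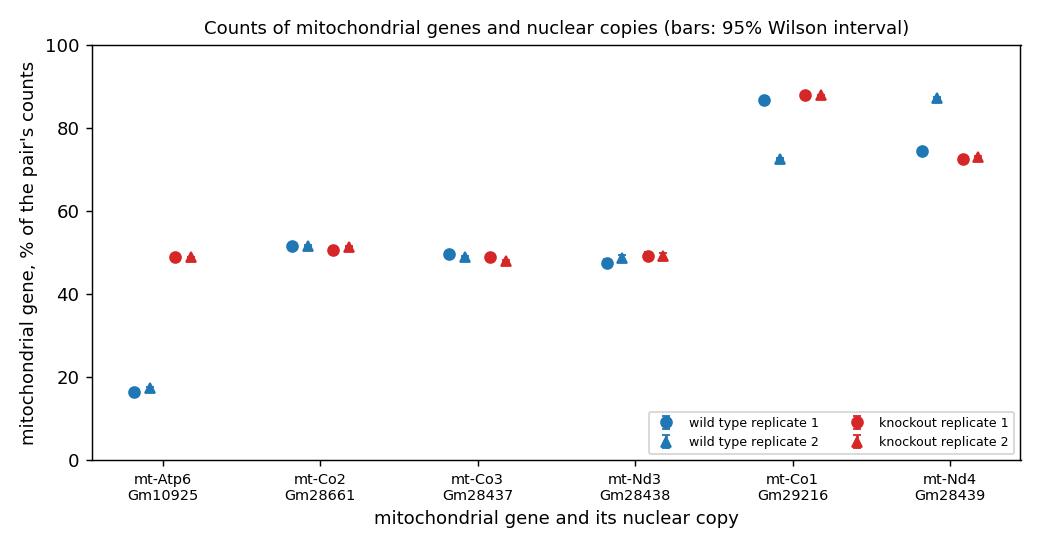
Share of the counts of each mitochondrial gene and its nuclear copy on chromosome 1 that the mitochondrial gene held, in percent, per library, with 95% Wilson intervals, circles for replicate 1, triangles for replicate 2, blue for wild type and red for the libraries labelled knockout. The mt-Atp6 pair differed by 31.9 percentage points between group means, against 8.17 at most in the 5 other pairs.

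Ribosomal protein genes and NRF2 targets were called lower, and both calls rested on wild type replicate 2. Of 39 ribosomal protein genes 33 were negative (median -0.48, camera adjusted p = 1.43e-03; adjusted p = 0.82 with an estimated correlation). Rps2, Rps14, Rpl37 and Rpl18 had log2 fold changes of -1.18, -0.92, -0.67 and -0.79, and such genes share reads with many pseudogenes. The median was -0.79 without wild type replicate 1 and 0.03 without wild type replicate 2, where Rps14, Rpl37 and Rpl18 were at -0.61, -0.35 and -0.18. Of 26 targets of NRF2, the transcription factor of the antioxidant response, 20 were negative (median -0.43, camera adjusted p = 8.75e-03; adjusted p = 0.82 with an estimated correlation). Hmox1, Gstm3, Gsta4 and Abcc4 had log2 fold changes of -1.08, -1.15, -2.3 and -1.35, and without wild type replicate 2 Gsta4 was at -0.33. The NRF2 median was -0.88 without wild type replicate 1, and the call was lost without wild type replicate 2 (-0.14), without knockout replicate 2 (-0.4) and at a filter of 5 CPM. No member of either list passed when adjusted over the list alone.

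The other 30 lists did not pass, with medians from -0.3 to 1.01 and a lowest camera adjusted p of 0.0597. Among them were the lists of hepatocyte identity, bile ducts, dendritic cells, cytotoxic cells, MHC class I presentation, cholesterol synthesis, p53 targets and immediate early genes, which respond to tissue handling. The highest median belonged to the sex-linked and sex-biased liver genes, with 15 of 22 members positive (camera adjusted p = 0.105). This list mixes genes biased to either sex, so its median and its count of positive members do not show the sex of the mice. The genes named from this list and from the next were chosen after their values were seen. Sult2a1 rose when adjusted over the list alone (log2 fold change 2.5, SE 0.49), and DESeq2 called Sult2a1 and Cyp2b9 higher, the latter at 4.2 with all libraries and 1.79 without knockout replicate 1. The list passed with library totals alone (adjusted p = 0.0485), without knockout replicate 1 (median 1.27) and without wild type replicate 2 (1.96), while its median was -0.24 without knockout replicate 2. Split by replicate number instead, 17 of its 22 members were higher in replicates 2 (camera adjusted p = 1.55e-05 at the preset correlation). The list for pancreas, adipose and gut carry-over was too small for camera, with 4 tested members, 4 of them negative (median -2.41). Vil1, Reg3g and Cela1 fell when adjusted over the list alone (smallest adjusted p = 9.66e-05). Reg3g moved from -3.12 to -1.64 and Cela1 from -1.7 to -0.89 without wild type replicate 2.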

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

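Leaving out the mitochondrial genes and their nuclear copies was tested only after the results were seen; the other settings were planned. Tfrc ranged from -0.79 to 0.17 over the fits without 1 library, with the reversal without wild type replicate 1, and kept its sign and its side of the threshold otherwise. The count of genes higher in knockout was 0 with edgeR and became 65 with DESeq2. The count lower was 0 and became 85 with DESeq2, 1 with limma-voom and 1 with library totals alone, the last 2 being Gm43305. Without 1 library the counts ranged from 0 to 209 higher and from 0 to 200 lower. The libraries share only a number across the groups; deviations of same-numbered libraries correlated at 0.121 across genes. With the replicate block 2 genes were called higher (Gm20716, Exosc6) and 2 lower (Gm43305, Vil1), 18 lists passed, the sex-biased liver genes among them (adjusted p = 2.27e-03), and Myc was at -0.018. The 16 lists past camera's threshold became 0 with an estimated correlation and 0 with fry, 14 to 18 in the other settings and 16 to 23 without 1 library. Of the 16, 10 were shared without wild type replicate 2, 12 without knockout replicate 2, 14 without wild type replicate 1 and 16 without knockout replicate 1. Of 98 genes recomputed, Myc (0.01) turned to -0.009 with DESeq2's size factors and with DESeq2, -0.032 with library totals and with no filter, and -0.019 with limma-voom. Over the fits without 1 library, 4 genes turned: Tfrc as above, Myc ranged from -0.41 to 0.31, Alb from -0.64 to 1.85 and Hspb1 from -2.46 to 0.66. Counting these, 43 of the 98 moved over 1.5 times, 24 of them without wild type replicate 2. Without 1 library, camera's direction turned for the MYC targets (medians from -0.2 to 0.055), the WNT targets (-1.41 to 1.47) and the ferroptosis list, whose medians stayed negative (-0.33 to -0.045). Medians alone also turned for the iron list (0.11) and ribosomal proteins (0.03) without wild type replicate 2, and for the sex-biased liver genes (-0.24) without knockout replicate 2. The cause of these changes was not tested. At this depth the spread between mice, with a common dispersion of 0.141, rather than counting error limits the named genes above a few CPM. A filter at a mean of 5 CPM removed Epo, Cybrd1, Retnlg, Mmp8, Vwf, Abcc4, Il7r, Bcl11b, Cd6, Cd5, Igha, Bank1, Cd79b, Cyp2b9 and Reg3g.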

Other observations

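The tests of the mt-Atp6, globin and interferon patterns below, the platelet list among them, were chosen only after the results, or counts of some of the genes, were seen. Beyond the comparisons above, 2 immunoglobulin genes stood higher in the libraries labelled knockout. Of 10 tested genes of B cells and plasma cells, 2 rose when adjusted over the list alone. Igha, the constant chain of immunoglobulin A, had 14 and 12 counts in wild type and 82 and 185 in knockout (log2 fold change 3.43, SE 0.62), and Igkc, the kappa light chain, had a log2 fold change of 2.06. Bank1 and Cd79b, of the B cell receptor pathway, had log2 fold changes of -2.16 and -1.14. The list did not pass camera (median 0.3, adjusted p = 0.364), but passed without knockout replicate 1 (median 1.27, adjusted p = 3.59e-03). Its median was 1.09 without wild type replicate 1 and 0.105 without knockout replicate 2, where Igkc was at 1.25.

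Targets of WNT and beta-catenin signalling in the liver went both ways between the groups, with 9 positive and 8 negative log2 fold changes among 17 tested genes (camera adjusted p = 0.689). Their median relative to each gene's mean was -0.97 and -0.81 in replicate 1 of wild type and knockout and 0.62 and 0.78 in replicate 2. Split by replicate number instead, 16 of the 17 were higher in replicates 2 (camera adjusted p = 2.78e-12 at the preset correlation, where 22 lists passed). By the labels the list passed, with medians of 1.47 and 1.05, without wild type replicate 2 and without knockout replicate 1. Genes that differed at least 8-fold between every library of 1 side and every library of the other numbered 19 for the labelled groups, 33 for replicates 1 against 2 and 7 for the crossed split.

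The share of counts that mt-Atp6 held against its nuclear copy Gm10925 separated the groups, by 31.9 percentage points between group means against 8.17 at most in the 5 other pairs of mitochondrial genes and nuclear copies. Within wild type, replicates 1 and 2 also differed in the shares of mt-Co1 (86.78% and 72.56%) and mt-Nd4 (74.5% and 87.15%). The mt-Atp6 share did not follow the mitochondrial content of the libraries. Wild type replicate 1 and knockout replicate 1 had 8.69% and 9.8% mitochondrial counts and yet differed by 32.3 percentage points in this share. Wild type replicates 1 and 2 had 8.69% and 4.13% mitochondrial counts, with shares of 16.5% and 17.3%. Because the pair was picked for its shares, this describes the same values and is not a separate test. Reads moved from one gene of the pair to the other were argued against as the whole source: relative to the median sum of the 5 other pairs, the summed counts of both genes were 0.517 and 0.521 in wild type and 1.16 and 1.13 in knockout (log2 ratio 1.14). In the other pairs this log2 ratio ran from -0.78 for mt-Co2 to 0.13 for mt-Nd4. Within wild type, however, the relative sums of replicates 1 and 2 were 0.878 and 1.92 for mt-Co3 and 1.14 and 0.467 for mt-Nd4. The measure thus varied about as much between 2 mice of a group, so the sums do not rule out moved reads. The sums of the mt-Co2 and mt-Nd3 pairs also did not overlap between the groups, with lower values in knockout. Reads lost from both genes, a difference in mitochondrial sequence between the maternal lines of the mice and an effect of Tfrc stay open and untested, since the 31.9 points were the reason the pair was examined and do not test how its reads were assigned.

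The 4 globin genes had a mean log2 fold change of -3.19. Wild type replicate 2, with the highest globin counts, was argued against as the only source, since the mean without it was -2.48. Less blood in the tumour samples of the knockout could lower them, but the median of 8 tested platelet genes, -0.62, did not decide: 5 were negative, among them Ppbp (-4.06), Pf4 (-2.49) and Itgb3 (-2.45), which DESeq2 called lower, while Gp1ba (1.4), Gp5 (1.28) and Itga2b (0.54) were positive and not called. Blood content and an effect of the genotype on red cells therefore cannot be told apart from these counts.

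The higher interferon-stimulated genes may reflect the genotype, a hypothesis found on these 4 mice and not tested on others. More leukocytes in the knockout samples was argued against, since the pan-leukocyte list had a median of -0.73 with 13 of 15 members negative. Wild type replicate 2 was not the only library on the low side, since the list median without it was 0.94, with 1 wild type mouse left. Relative to each gene's mean, the list medians were -0.28 and -0.92 in wild type replicates 1 and 2, and 0.77 and 0.28 in knockout. The wild type mice thus lay further apart than wild type replicate 1 and knockout replicate 2, so differences between single mice were not excluded. A change in T cells, whose list was no longer called without wild type replicate 2, or an infection of the knockout mice stays open and was not tested.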
